A study of Mus musculus with 167 samples.

How the data were processed

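The 167 libraries were of mouse cells: MEFs of the C9a line (homozygous Clec9a Cre, Rosa26 tdTomato) and the hCD2 line (hCD2 Cre, Rosa26 YFP), MEFs transduced with PIB, PIP or SII lentivirus and sorted on day 3, 6 or 9, and splenic cDC1, cDC2 and pDC. Per the labels' protocols, RNA came from 5000 sorted cells per extraction, cDNA was made with a stranded total RNA kit for picogram input and amplified over 13 to 14 cycles, and sequencing ran on a NovaSeq X. The deposited values are whole-number counts per Ensembl gene, for 57010 identifiers. Per the submitters the build was mm10 and the tools were STAR 2.7.9a and Salmon 1.10.1. Which of them gave the counts, the annotation release and the strand setting are not given, so overlapping and antisense genes and near-identical copies, such as Oas1a and its neighbours, may share reads. Identifiers were named from the GENCODE M21 gene names, which held 52029 of them, and 4981 had no name. Those took a median of 13.2% of the counts (5.98 to 32.1%), most of it in a single identifier (median 10.1%, 4.38 to 30.1%). They stayed in the fits and in library totals and were not reported.

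Of the libraries 165 had over 2000000 counts. Groups were the 41 combinations of line, cocktail, day and sort gate in the labels. No library was left out of its group. Day 6 groups, day 3 groups of single gates and the 3 libraries whose factors contradict their label entered only the alternative fit over all groups. Of 266 pairs of libraries within a group none were copies: chi-square per degree of freedom was at least 2.68, with a median of 27.3.

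The 27 comparisons were made with edgeR 4.0.16 in R 4.3.3, each on the libraries of its own groups: TMM factors, filterByExpr by group, robust dispersions, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold. Levels are TMM-scaled CPM within a comparison, and CPM of the total elsewhere. Gene lists of at least 3 tested members were tested with camera of limma 3.58.1 on the z-scores of each fit at a preset correlation of 0.01, and again with a correlation estimated from the list and with fry, adjusted within each comparison. There were 31 lists, for transduced factors, sort markers, dendritic and other cell types, antigen presentation, interferon, fibroblast, proliferation, stress and metabolism genes. Splenic sets held the genes called higher in one splenic subset than in each of the others: 521 for cDC1, 876 for cDC2 and 773 for pDC. They were tested only in comparisons without spleen libraries. Scores are the mean log2 CPM (prior count 2) over a set in each library, compared between days by exact permutation. Comparisons that share C9a.MEF were set against 20 rounds of simulated unchanged groups.

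Named genes followed a rule: the factors and sort markers in every comparison, from each list the called members with the largest changes whose libraries did not overlap (up to 4 against MEFs and between cocktails, otherwise 2), the largest in the other direction and the most abundant uncalled, and from all called genes of at least 10 CPM the 5 highest and 5 lowest (otherwise 3 and 3), leaving out predicted genes. A few genes that the rule allows are not reported here. Comparisons, lists, this rule and the alternatives were fixed before the data were examined, except where a choice is said to have come after.

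The alternatives were DESeq2 1.42.0 size factors, no low-count filter, the DESeq2 Wald test, replicate number as a block, 1 fit over all groups, leaving out each library in turn, a prior count of 0.5, 4-fold splenic sets, correlations over fewer genes, and, chosen later, calls of at least 10 CPM and comparisons without libraries under 2000000 counts or, in a CD45 gate, under 5 CPM of Ptprc. The labels give replicate numbers no meaning. Correlations of the deviations from the group mean between same-numbered libraries were over 0.1 for every pair in 2 of 26 comparisons: hCD2.SII against hCD2.MEF (lowest 0.109 over 3 pairs) and hCD2.SII double positive against CD45-gated cells (0.353 to 0.610).

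The tests were tested on simulated counts with 200 changed genes. For PIB against MEF edgeR called 98.5% of genes changed 4-fold, 46.3% of those changed 2-fold and 0.0195% of unchanged genes, for hCD2.SII against MEF 89.4%, 10.4% and 0.0542%, and for PIB against PIP 97.0%, 44.8% and 0%.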

Results

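RNA from mouse embryonic fibroblasts (MEFs), from MEFs transduced with lentivirus for combinations of dendritic cell transcription factors, and from splenic dendritic cells was sequenced. PIB stood for Spi1 (PU.1), Irf8 and Batf3, PIP for Spi1, Irf4 and Prdm1, and SII for Spib, Irf8 and Ikzf2. PIB and PIP were put into MEFs of the C9a line, in which Cre from the Clec9a locus switches on tdTomato, and SII into that line (C9a.SII) and into the hCD2 line, which carries a YFP reporter (hCD2.SII). Transduced cells were sorted on days 3, 6 and 9 by the reporter, by CD45 or by both (double positive), with 3 to 5 libraries in each of the 41 groups. The controls were untransduced C9a.MEF (n = 4) and hCD2.MEF (n = 4), and splenic conventional dendritic cells of type 1 (cDC1, n = 3) and type 2 (cDC2, n = 3) and plasmacytoid dendritic cells (pDC, n = 5). Total counts ran from 1146927 to 21976374 per library (median 10960122). Values after ± are standard deviations for levels in CPM (counts scaled to a common total per library) and standard errors for log2 fold changes. A gene rose or fell where edgeR gave an adjusted p under 0.05 and a change of at least 2-fold. Named genes that rose or fell had every library of one group above every library of the other, and none lost its call under another setting unless the text gives it. Gene values without a unit are log2 fold changes of the first-named group over the second, and where a group was at or near 0 the levels are given instead. Beside a list stand the counts of its tested members that were higher or lower, the rest having been neither, and the adjusted p of camera at a preset correlation between genes. A second p follows where a correlation estimated from the list ended the call (if estimated), and a second pair of counts where adjusting over the list alone changed them (within it). Percentages of genes higher or lower are of those tested. A count of 0 in a library allows up to 0.137 to 2.62 CPM at these totals, by counting error only.

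The transduced factors followed the cocktail in the labels in all but 3 libraries. In the other 36 PIB libraries Spi1 ranged from 101.4 to 289 CPM, Irf8 from 91.1 to 272 CPM and Batf3 from 13.6 to 40.5 CPM, while Irf4 was at most 1.67 CPM and Spib at most 0.559 CPM. In 37 PIP libraries Irf4 ranged from 193 to 786 CPM and Prdm1 from 208 to 1014 CPM. Spib was at most 4.56 CPM in them, in the day 6 CD45+ group, where Irf8 reached 12.4 CPM (median 2.95 CPM). Ikzf2 ranged from 214 to 1216 CPM in 37 C9a.SII libraries and from 72.8 to 1452 CPM in 35 hCD2.SII libraries, with Spib from 27.2 to 219.5 and from 11.7 to 260.4 CPM, against at most 0.268 CPM in C9a.MEF and 0.168 CPM in hCD2.MEF. Median Irf8 was 138.7 CPM in PIB and 1921 CPM in splenic cDC1, and median Irf4 403 CPM in PIP and 88.5 CPM in splenic cDC2. The library labelled PIB day 6 tdT+ replicate 4 held Irf4 at 539 CPM and Prdm1 at 639 CPM, with Batf3 at 1.45 CPM. The library labelled PIP day 3 tdT+ replicate 5 held Spib at 112.4 CPM and Ikzf2 at 523 CPM, with Irf4 at 3.94 CPM. The library labelled C9a.SII day 6 tdT+ replicate 5 held Irf4 at 658 CPM and Prdm1 at 773 CPM, with Spib at 0.405 CPM. The 3 entered gene comparisons only in the fit of all groups.

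**Figure D1:**
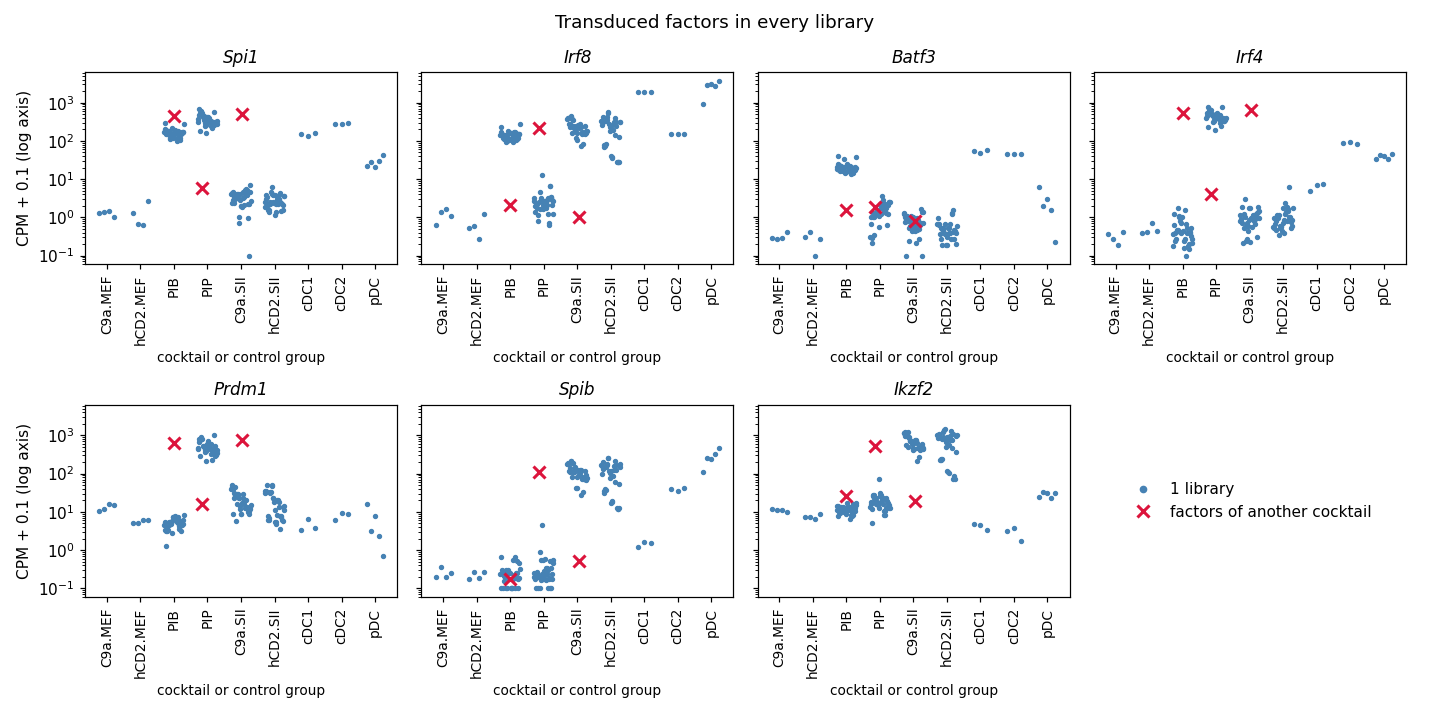
Levels of the 7 transduced factors (y axis, CPM plus 0.1 on a log axis) in every library, by cocktail or control group (x axis). Points are libraries, and crosses mark the 3 with factors of another cocktail.

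The first question was how sorted day 9 cells differed from untransduced fibroblasts of their own line. Cocktail, transduction, culture and sorting cannot be told apart here. In PIB double positive cells (n = 5 and 4) the factors stood at 193 ± 42.1 against 1.16 ± 0.191 CPM for Spi1, 170.3 ± 54.1 against 1.07 ± 0.427 CPM for Irf8 and 22.7 ± 7.66 against 0.209 ± 0.0624 CPM for Batf3. Of the sort markers, Ptprc (CD45) reached 222 ± 40.3 against 0.282 ± 0.0974 CPM, the cDC1 chemokine receptor Xcr1 133.3 ± 5.43 against 0.0417 ± 0.0485 CPM, Itgam (CD11b) 115.3 ± 12.3 against 3.69 ± 0.589 CPM and the class II chain H2-Aa 69.9 ± 17.3 against 0.0667 ± 0.0445 CPM, while Itgax (CD11c) stood at only 1.35 ± 0.494 against 0.0823 ± 0.0622 CPM. Together the sort markers had 5 of 6 higher (adjusted p = 1.4e-14) and the 7 factors 3 of 5 higher and 1 lower (adjusted p = 4.4e-04, adjusted p = 0.168 if estimated). Of the cDC1 markers 11 of 13 were higher and 1 lower (adjusted p = 5.7e-10). Rab7b had 3.59 ± 0.08, Naaa 3.53 ± 0.18 and Cd24a -2.63 ± 0.10. The cDC2 markers also moved: 9 of 12 were higher and 2 lower (adjusted p = 1.4e-12), among them the lectin Clec12a at 219 ± 9.62 against 0.0852 ± 0.0714 CPM and the chemokine receptor Ccr2 at 152.4 ± 26.5 against 0.0856 ± 0.00686 CPM. The pDC markers had 5 of 12 higher and 1 lower (adjusted p = 0.246). The pan-dendritic list had 4 of 9 higher (adjusted p = 0.194, 0.00811 without PIB day 9 replicate 5). Pan-leukocyte genes rose: 14 of 17 were higher and 1 lower (adjusted p = 1.0e-15), with Plek at 241 ± 13.4 against 1.13 ± 0.488 CPM and the actin regulator Lsp1 at -2.94 ± 0.12.

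Among the class II presentation genes 8 of 9 were higher (adjusted p = 2.2e-10), including the invariant chain Cd74 at 748 ± 218 against 0.256 ± 0.1597 CPM and the cysteine protease Ctss at 170.3 ± 34.4 against 0 ± 0 CPM. Of the class I genes 8 of 16 were higher (adjusted p = 2.4e-07). H2-K1 had 1.49 ± 0.07 and H2-D1 1.41 ± 0.05. Macrophage and monocyte markers rose too: 10 of 14 were higher (adjusted p = 3.4e-07), with lysozyme Lyz2 at 822 ± 90.1 against 1.004 ± 0.0936 CPM. Lysosomal genes had 10 of 18 higher (adjusted p = 4.0e-11, adjusted p = 0.0664 if estimated). Ctsh had 2.79 ± 0.08 and Lgmn 1.89 ± 0.11. Fibroblast genes were lower: 19 of 28 were lower and 1 higher (adjusted p = 1.1e-19), with log2 fold changes of -3.46 ± 0.15 for Fbln2, -2.96 ± 0.12 for Lum and -2.83 ± 0.07 for Col6a1, against 1.07 ± 0.06 for the metalloproteinase inhibitor Timp2, while Col1a2 stood at 4365 ± 436 against 3841 ± 137.7 CPM. In the contractile list, which holds smooth muscle actin, 11 of 12 were lower (adjusted p = 7.3e-13). Acta2 had -3.81 ± 0.18 and Tagln -4.31 ± 0.21. Proliferation genes were lower: 19 of 20 were lower (adjusted p = 3.5e-25) for G2 and M phase, with -4.30 ± 0.16 for Mki67, and 14 of 20 were lower (adjusted p = 1.2e-12) for S phase. In cholesterol biosynthesis 9 of 18 were lower (adjusted p = 1.4e-07). Interferon-stimulated genes had 13 of 28 lower and 2 higher (adjusted p = 5.7e-09). Rtp4 had -2.97 ± 0.09, Cxcl10 -2.75 ± 0.13 and Mx1 2.002 ± 0.17. Toll-like receptor genes had 9 of 17 higher (adjusted p = 5.3e-05), with 3.78 ± 0.09 for Tlr4. Over all 15776 genes tested, 1644 were higher and 1794 lower in PIB cells (974 and 886 at 10 CPM or more). Counts within a list alone were the same unless given.

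Lists for other cell types and stress were also tested in PIB cells. The unfolded protein response list had 0 of 13 higher or lower (adjusted p = 0.485), p53 targets 1 of 14 lower (adjusted p = 0.650), immediate early genes 2 of 11 higher and 1 lower (adjusted p = 0.408, 0.0362 without a low-count filter) and mitochondrially encoded transcripts 0 of 13 higher or lower (adjusted p = 0.485, 9.6e-04 without PIB day 9 replicate 5). Granulocyte markers had 2 of 3 higher and 1 lower (adjusted p = 0.955), endothelial markers 2 of 4 lower and 1 higher (adjusted p = 0.720), epithelial markers 1 of 3 lower (adjusted p = 0.485), muscle markers 3 of 4 lower (adjusted p = 0.0970), erythroid and platelet markers 0 of 3 higher or lower (adjusted p = 0.720), B cell markers 0 of 2 higher or lower and T and NK cell markers 1 of 2 higher. The splenic sets were tested too. For cDC1-specific genes 30.1% of 409 were higher and 32 lower (adjusted p = 3.4e-06). For cDC2-specific genes 206 of 701 were lower and 20.1% higher (adjusted p = 0.130, 0.0417 without pDC replicate 1). For pDC-specific genes 81 of 560 were lower and 80 higher (adjusted p = 0.720, 81 higher and 81 lower within it).

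In PIP double positive cells against the same fibroblasts (n = 4 and 4) the factors stood at 334 ± 19.6 against 1.1004 ± 0.183 CPM for Spi1 and 395 ± 18.02 against 0.197 ± 0.0899 CPM for Irf4, and the third, Prdm1, rose by 5.004 ± 0.13. Sort markers rose to 331 ± 45.3 CPM for Itgam, 84.04 ± 16.8 CPM for Ptprc, 82.4 ± 4.12 CPM for Itgax and 11.6 ± 2.96 CPM for H2-Aa, against 3.495 ± 0.562, 0.268 ± 0.0925, 0.0779 ± 0.0588 and 0.0633 ± 0.0422 in MEFs. Cd209a, a lectin of cDC2 and monocyte-derived cells, stood at 454 ± 14.9 against 0.0206 ± 0.0412 CPM. Of the cDC2 markers 7 of 12 were higher and 2 lower (adjusted p = 2.2e-11). Of the cDC1 markers 10 of 11 were higher and 1 lower (adjusted p = 4.1e-10), with 3.64 ± 0.10 for the adhesion molecule Cadm1. Of the pDC markers 9 of 14 were higher and 1 lower (adjusted p = 0.00161), with Klra17 at 183 ± 15.2 against 0.105 ± 0.0808 CPM. Pan-leukocyte genes had 17 of 20 higher and 1 lower (adjusted p = 5.2e-15), with the actin bundler Lcp1 at 219 ± 4.92 against 0.381 ± 0.261 CPM. The pan-dendritic list had 5 of 9 higher (adjusted p = 3.0e-05), with 3.41 ± 0.16 for the conventional dendritic cell factor Zbtb46. In class II presentation 6 of 9 were higher (adjusted p = 4.0e-07, adjusted p = 0.0932 if estimated), with Cd74 at 342 ± 15.2 against 0.242 ± 0.151 CPM, and in class I 13 of 16 were higher (adjusted p = 2.7e-14). H2-K1 had 3.18 ± 0.06 and H2-D1 2.55 ± 0.06.

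The fibroblast list fell almost as a whole: 26 of 28 were lower and 1 higher (adjusted p = 6.2e-52). Lum had -6.38 ± 0.12, Col3a1 -6.29 ± 0.10 and Fbn1 -5.46 ± 0.07. Contractile genes had 10 of 12 lower (adjusted p = 3.6e-15), with -5.21 ± 0.10 for Acta2. G2 and M phase genes had 18 of 20 lower and 1 higher (adjusted p = 2.2e-09, adjusted p = 0.0774 if estimated), with -4.18 ± 0.15 for Mki67. S phase genes had 15 of 20 lower (adjusted p = 5.2e-06, adjusted p = 0.163 if estimated), with -4.36 ± 0.14 for Uhrf1. Lysosomal genes had 12 of 18 higher and 1 lower (adjusted p = 1.1e-13, adjusted p = 0.0510 if estimated). Lgmn had 4.32 ± 0.07 and Ctsd 4.01 ± 0.07. Macrophage markers had 10 of 13 higher and 1 lower (adjusted p = 0.00108, adjusted p = 0.0902 if estimated), with the scavenger receptor Marco at 39.04 ± 17.5 against 0.106 ± 0.0820 CPM. Interferon-stimulated genes went both ways: 7 of 28 were higher and 4 lower (adjusted p = 0.171), from 4.23 ± 0.16 for Mx1 to -1.83 ± 0.12 for Ifit3. Costimulation genes had 9 of 15 higher and 1 lower (adjusted p = 0.00212, adjusted p = 0.0510 if estimated), with the chemokine Ccl22 at 17.4 ± 0.877 against 0.0394 ± 0.0459 CPM. Outside the lists the chemokine Ccl12 reached 709 ± 47.5 against 0.0816 ± 0.0693 CPM and the lectin Cd209e 223 ± 15.6 against 0 ± 0 CPM, while the growth factor Ptn had -7.08 ± 0.08. Of the splenic sets, 230 of 699 were lower and 177 higher (adjusted p = 0.816) of the cDC2-specific genes, 36.6% of 402 were higher and 49 lower (adjusted p = 5.5e-06) of the cDC1-specific and 20.1% of 562 were higher and 96 lower (adjusted p = 0.835) of the pDC-specific. In all, 2379 genes were higher and 2271 lower of 15693 tested.

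In C9a.SII double positive cells against C9a.MEF (n = 4 and 4) Spib and Irf8 stood at 94.9 ± 35.6 against 0.148 ± 0.0810 CPM for Spib and 202 ± 65.97 against 1.07 ± 0.420 CPM for Irf8, and Ikzf2 rose by 5.68 ± 0.19. Ptprc reached 153.1 ± 42.1 against 0.282 ± 0.0970 CPM, with Itgax at 6.57 ± 2.496 against 0.0818 ± 0.0618 CPM and Itgam at 88.5 ± 19.4 against 3.68 ± 0.614 CPM, while Bst2, a pDC marker that interferon also raises, fell (-1.82 ± 0.07). Pan-leukocyte genes had 19 of 21 higher and 1 lower (adjusted p = 2.7e-11, adjusted p = 0.0685 if estimated), with Laptm5 at 101.8 ± 11.4 against 0.185 ± 0.167 CPM. Of the pDC markers 3 of 10 were higher and 2 lower (adjusted p = 0.310), among them Tlr9, a receptor for CpG DNA, at 6.23 ± 1.75 against 0.111 ± 0.0844 CPM. The cDC1 list had 5 of 10 higher and 3 lower (adjusted p = 0.137, 0.00731 without C9a.SII day 9 replicate 1). Id2 had 2.93 ± 0.11, Naaa 2.79 ± 0.24 and Tlr3 -2.72 ± 0.34. The cDC2 list had 5 of 10 higher and 2 lower (adjusted p = 0.186, 0.0111 without C9a.SII day 9 replicate 1), with Clec12a at 86.8 ± 24.7 against 0.0849 ± 0.0715 CPM. The class II invariant chain Cd74 stood at 100.5 ± 16.2 against 0.254 ± 0.157 CPM. Macrophage markers had 8 of 11 higher (adjusted p = 1.8e-04, adjusted p = 0.187 if estimated), and the inhibitory receptor Pirb, outside the lists, stood at 223 ± 22.96 against 0.110 ± 0.132 CPM.

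Interferon-stimulated genes had 24 of 28 lower (adjusted p = 2.0e-15, adjusted p = 0.124 if estimated). Oasl2 had -5.80 ± 0.17, Ddx60 -4.82 ± 0.22, Ifit1 -4.57 ± 0.51 and Isg15 -4.53 ± 0.26. Inflammatory cytokines had 7 of 11 lower (adjusted p = 2.8e-04, adjusted p = 0.0850 if estimated). Cxcl1 had -4.71 ± 0.29 and Cxcl10 -3.38 ± 0.27. Of the fibroblast genes 24 of 28 were lower and 2 higher (adjusted p = 8.5e-14). Col6a3 had -5.30 ± 0.28, Pdgfra -4.72 ± 0.24, Col3a1 -3.78 ± 0.16 and Fn1 1.65 ± 0.21. G2 and M phase genes had 18 of 20 lower (adjusted p = 1.2e-08, adjusted p = 0.259 if estimated), with -2.87 ± 0.14 for the checkpoint kinase Bub1b. S phase genes had 14 of 20 lower (adjusted p = 5.7e-06, adjusted p = 0.196 if estimated), with -1.99 ± 0.24 for Mcm5. Of the splenic sets, 73 of 556 were lower and 70 higher (adjusted p = 0.975, 71 higher and 73 lower within it) of the pDC-specific genes. In all, 1638 genes were higher and 1708 lower of 15661 tested. Replicate 1 of these C9a.SII libraries held 1146927 counts and a raised share of olfactory and vomeronasal receptor counts, 1.98% against 0.196 to 0.260% in the others.

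In hCD2.SII double positive cells against hCD2.MEF (n = 3 and 4) the factors stood at 125.7 ± 64.4 against 0.123 ± 0.0522 CPM for Spib and 257 ± 112.4 against 0.550 ± 0.400 CPM for Irf8, and Ikzf2 rose by 6.72 ± 0.40. Ptprc reached 191 ± 106.8 against 0.108 ± 0.0843 CPM, with Clec9a at 5.40 ± 3.69 against 0.0806 ± 0.0705 CPM and Itgam at 131.6 ± 78.2 against 6.78 ± 3.75 CPM. Pan-leukocyte genes had 15 of 18 higher and 1 lower (adjusted p = 4.0e-25, adjusted p = 0.0927 if estimated), with Laptm5 at 65.0004 ± 20.7 against 0.253 ± 0.201 CPM. Of the pDC markers 4 of 12 were higher (adjusted p = 0.00171, adjusted p = 0.125 if estimated), with Tlr9 at 6.57 ± 2.34 against 0.0936 ± 0.0849 CPM and the B cell adaptor Blnk at 6.92 ± 4.38 against 0.116 ± 0.0604 CPM. The cDC2 list had 6 of 12 higher (adjusted p = 5.0e-04, adjusted p = 0.139 if estimated, 6 higher and 1 lower within it), with Clec12a at 52.4 ± 11.96 against 0.0223 ± 0.0445 CPM, and Cd74 stood at 52.7 ± 21.96 against 0.219 ± 0.210 CPM. The log2 fold changes of the cDC1 markers Id2 and Ppt1 were 3.29 ± 0.30 and 2.10 ± 0.17. Macrophage markers had 8 of 9 higher (adjusted p = 5.5e-09, adjusted p = 0.0815 if estimated). Cd68 had 4.18 ± 0.41. G2 and M phase genes had 18 of 20 lower (adjusted p = 1.4e-11, adjusted p = 0.212 if estimated, 0 higher and 19 lower within it), with -3.40 ± 0.61 for the mitotic kinesin Kif20a. S phase genes had 15 of 20 lower (adjusted p = 4.6e-14, adjusted p = 0.139 if estimated). Mcm5 had -3.15 ± 0.36 and Mcm6 -2.39 ± 0.40. Cholesterol biosynthesis had 12 of 18 lower (adjusted p = 2.1e-08, adjusted p = 0.198 if estimated), with -2.28 ± 0.30 for Idi1. Of the fibroblast genes 5 of 28 were lower and 2 higher (adjusted p = 0.00200, adjusted p = 0.609 if estimated, 2 higher and 0 lower within it). Of the interferon-stimulated genes 2 of 28 were lower (adjusted p = 6.0e-05, adjusted p = 0.581 if estimated, 0 higher and 1 lower within it), with -1.72 ± 0.33 for Oas3. The splenic pDC-specific set had 84 of 566 higher and 49 lower (adjusted p = 0.248, 85 higher and 49 lower within it). In all, 1780 genes were higher and 1384 lower of 16448 tested, but 3071 higher and 2762 lower without hCD2.SII day 9 replicate 1. In that library Col1a1, a fibroblast collagen, stood at 2801 CPM, against 145.9 and 101.8 CPM in replicates 2 and 3. Replicate number as a block, which the numbers in this comparison would allow, gave 1512 higher and 1195 lower.

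The 3 C9a cocktails were compared with the same 4 C9a.MEF libraries, and of 14915 genes tested in all of them 470 were higher in all, against 13.98 if independent, and 798 lower, against 30.8. PIB and PIP shared 891 higher genes, against 187 if independent, and 1210 lower, against 266. Across genes, which are not independent replicates, their log2 fold changes had r = 0.737 and a covariance of 1.42. Simulated counts with no change gave a mean r of 0.539 and covariance of 0.0429 from the shared controls alone, and 0 shared calls. With separate pairs of the controls r was 0.711 and 0.690, the covariance 1.45 and 1.42, and the shared higher genes 911 and 888. For PIB and C9a.SII r was 0.641 (simulated 0.510, split controls 0.623 and 0.607) with a covariance of 0.981 (simulated 0.0421), and for PIP and C9a.SII r was 0.603 (simulated 0.491, split controls 0.593 and 0.594) with a covariance of 1.09 (simulated 0.0420). C9a.SII and hCD2.SII share no control and had r = 0.818, with 1068 genes higher in both, against 158.7 if independent, 851 lower, against 147.1, and 3 opposite.

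Whether SII acted differently in the C9a and hCD2 lines was tested as an interaction, with the sort reporter differing too. Of 17789 genes 32 had a higher and 69 a lower change in the C9a line (2433 at an unadjusted p under 0.05), and with DESeq2 size factors 42.2% of calls were higher against 31.7%. The fit of all groups turned the balance to 78 and 29. The difference in log2 fold change was 3.87 ± 0.45 for skeletal actin Acta1 and -2.85 ± 0.18 for the neurotrophic factor receptor Gfra1. The transduced factors differed by -1.34 ± 0.67 for Irf8, -0.74 ± 1.13 for Spib and -1.08 ± 0.37 for Ikzf2, with adjusted p = 0.397, 0.822 and 0.218, and without hCD2.SII day 9 replicate 1 Ikzf2 was called, at -1.41. Interferon-stimulated genes, with 24 of 28 lower in one line and 2 of 28 in the other, had 0 of 28 higher or lower (adjusted p = 0.283, but up without hCD2.SII day 9 replicate 1, adjusted p = 2.0e-14 and median 1.24, and down without replicates 2 and 3, adjusted p = 3.0e-04 and 2.4e-04 and medians -1.09 and -1.06) in the test of the difference. Contractile genes had 1 of 12 higher (adjusted p = 2.1e-10, adjusted p = 0.314 if estimated, 3 higher and 0 lower within it). The counts rested on single libraries. Without C9a.MEF replicates 1 to 4 in turn, 21, 18, 15 and 23 were higher and 41, 40, 31 and 38 lower. Without hCD2.MEF replicates 1 to 4 in turn, 20, 17, 21 and 21 were higher and 41, 34, 38 and 38 lower. Without C9a.SII day 9 replicates 1, 3 and 4 in turn, 74, 22 and 24 were higher and 0.665%, 45 and 38 lower. Without hCD2.SII day 9 replicate 1, 607 were higher and 204 lower.

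The second question was whether the cocktails differed at day 9 in the same line. Between PIB and PIP (n = 5 and 4) the factors separated as transduced, with log2 fold changes of 6.17 ± 0.34 for Irf8, 3.12 ± 0.24 for Batf3 and -6.18 ± 0.14 for Prdm1 and Irf4 at 0.244 ± 0.127 against 385 ± 22.8 CPM. Xcr1 stood at 125.3 ± 4.996 against 0.121 ± 0.103 CPM and Cd209a at 0.0966 ± 0.174 against 443 ± 20.2 CPM. Other sort markers had 2.52 ± 0.23 for H2-Aa, -6.02 ± 0.14 for Itgax, -1.57 ± 0.10 for Itgam and -1.96 ± 0.09 for Bst2. Class II genes were higher in PIB: 7 of 10 were higher (adjusted p = 0.0235, adjusted p = 0.592 if estimated), with 4.65 ± 0.40 for H2-Ab1 and 2.45 ± 0.35 for Ciita, the second being the class II transactivator. Class I genes were lower: 6 of 16 were lower (adjusted p = 6.8e-07, adjusted p = 0.0908 if estimated). H2-K1 had -1.66 ± 0.07 and B2m -1.15 ± 0.07. Of the cDC1 markers 5 of 14 were higher and 4 lower (adjusted p = 0.975), with -5.84 ± 0.18 for Wdfy4 and -4.82 ± 0.10 for Cd24a, Wdfy4 being needed for cross-presentation. Of the cDC2 markers 4 of 13 were higher and 2 lower (adjusted p = 0.540), with 1.68 ± 0.06 for Clec12a. Of the pDC markers 8 of 16 were lower and 2 higher (adjusted p = 0.0179, adjusted p = 0.107 if estimated), with -4.89 ± 0.15 for Klra17. Fibroblast genes were higher in PIB: 22 of 28 were higher (adjusted p = 1.2e-30). Fn1 had 4.98 ± 0.12, Col3a1 3.76 ± 0.10 and Lox 3.64 ± 0.15. Interferon-stimulated genes were lower: 18 of 28 were lower (adjusted p = 5.9e-16). Rtp4 had -3.19 ± 0.09, Isg15 -2.49 ± 0.08 and Mx1 -2.20 ± 0.11. Cholesterol genes had 8 of 18 lower (adjusted p = 2.7e-06). Insig1 had -2.39 ± 0.12. Pan-leukocyte genes split: 9 of 21 were lower and 5 higher (adjusted p = 6.6e-04, adjusted p = 0.181 if estimated), with -6.90 ± 0.10 for Lcp1. Lysozyme Lyz2, a myeloid gene, had 9.12 ± 0.28 and the costimulator Cd40 -4.34 ± 0.13. The splenic sets had 91 of 423 lower and 77 higher (adjusted p = 0.584, 78 higher and 93 lower within it) for cDC1 and 17.3% of 684 lower and 16.4% higher (adjusted p = 0.595) for cDC2. In all, 1665 genes were higher and 1732 lower in PIB of 15733 tested (917 and 815 at 10 CPM or more).

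Between PIB and C9a.SII (n = 5 and 4) the factors had 5.47 ± 0.42 for Spi1, 4.50 ± 0.35 for Batf3 and -5.31 ± 0.20 for Ikzf2, with Spib at 0.150 ± 0.143 against 92.8 ± 34.8 CPM and Irf8, which the cocktails share, at 166.3 ± 53.03 against 198 ± 64.6 CPM. Xcr1 differed by 6.52 ± 0.20 and H2-Aa by 5.13 ± 0.40. Class II genes were higher in PIB, 8 of 9 higher (adjusted p = 1.1e-07, adjusted p = 0.0900 if estimated). The cDC2 markers had 9 of 14 higher and 1 lower (adjusted p = 3.3e-04, adjusted p = 0.115 if estimated, 9 higher and 2 lower within it). Ccr2 had 6.37 ± 0.21 and Fcgr2b 6.35 ± 0.37. Class I genes had 6 of 16 higher (adjusted p = 1.1e-07, adjusted p = 0.0900 if estimated). H2-K1 had 2.32 ± 0.14 and B2m 1.62 ± 0.15. Interferon-stimulated genes had 21 of 28 higher and 1 lower (adjusted p = 5.2e-15, adjusted p = 0.0900 if estimated). Zbp1 had 4.40 ± 0.10, Ifit2 3.78 ± 0.15 and Oasl2 3.70 ± 0.15. Cytokines had 12 of 16 higher and 1 lower (adjusted p = 1.6e-05, adjusted p = 0.0900 if estimated), with 4.13 ± 0.21 for Cxcl16. Pan-leukocyte genes were lower in PIB: 11 of 22 were lower and 2 higher (adjusted p = 3.4e-05, adjusted p = 0.0900 if estimated, 2 higher and 12 lower within it), with -4.63 ± 0.23 for the signalling adaptor Vav1, against 3.84 ± 0.15 for Ikzf1. Fibroblast genes had 13 of 28 higher and 2 lower (adjusted p = 5.7e-06, adjusted p = 0.0900 if estimated), with 4.28 ± 0.34 for Col6a3, 3.15 ± 0.15 for Bgn and 2.76 ± 0.12 for Col1a2, while the contractile genes Tagln and Acta2 had -3.08 ± 0.23 and -2.19 ± 0.18. The macrophage gene Adgre1 (F4/80) had -5.12 ± 0.34 and Lyz2 3.71 ± 0.60. In all, 1375 genes were higher and 1593 lower in PIB of 16052 tested (885 and 674 at 10 CPM or more).

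Between PIP and C9a.SII (n = 4 and 4) the factors had 6.35 ± 0.48 for Spi1, 5.01 ± 0.13 for Prdm1, -6.38 ± 0.35 for Irf8 and -5.15 ± 0.19 for Ikzf2, with Irf4 at 384 ± 18.3 against 1.31 ± 0.492 CPM and Spib at 0.269 ± 0.191 against 87.7 ± 32.1 CPM. Sort markers had 3.88 ± 0.20 for Itgax, 3.10 ± 0.12 for Bst2, 2.64 ± 0.43 for H2-Aa and 1.96 ± 0.17 for Itgam. Class I genes were almost all higher in PIP: 15 of 16 were higher (adjusted p = 2.5e-10, adjusted p = 0.147 if estimated). H2-K1 had 3.998 ± 0.17 and B2m 2.78 ± 0.16. Interferon-stimulated genes had 26 of 28 higher (adjusted p = 1.3e-18, adjusted p = 0.147 if estimated). Zbp1 had 5.55 ± 0.11, Mx1 5.45 ± 0.32 and Ifit2 5.35 ± 0.17. The cDC2 markers had 7 of 13 higher (adjusted p = 0.00754, adjusted p = 0.325 if estimated), with 8.33 ± 0.28 for Cd209a. Fibroblast genes were lower on balance: 17 of 27 were lower and 3 higher (adjusted p = 0.00180, adjusted p = 0.225 if estimated), from -6.03 ± 0.28 for Fn1 to 4.83 ± 0.28 for Col6a3. The lysosomal proteases Lgmn and Ctsd had 3.71 ± 0.14 and 3.34 ± 0.12, Acta2 -3.59 ± 0.14, Lyz2 -5.42 ± 0.86 and Adgre1 -4.48 ± 0.43. In all, 1715 genes were higher and 1809 lower in PIP of 15679 tested (1134 and 978 at 10 CPM or more).

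Splenic subsets set the scale of differences between dendritic cells. In cDC1 against cDC2 (n = 3 and 3) the log2 fold changes were 3.67 ± 0.08 for Irf8, -3.80 ± 0.15 for Irf4 and -4.83 ± 0.23 for Spib, and 6.10 ± 0.14 for Xcr1, 5.03 ± 0.10 for Clec9a, -4.61 ± 0.12 for Itgam and -1.65 ± 0.07 for Ptprc. Of the cDC1 markers 17 of 18 were higher (adjusted p = 3.1e-33), with 7.79 ± 0.30 for Itgae and 6.25 ± 0.18 for Cadm1. Of the cDC2 markers 16 of 19 were lower and 1 higher (adjusted p = 4.0e-20). Interferon-stimulated genes were lower in cDC1: 19 of 28 were lower and 1 higher (adjusted p = 4.9e-11), with -6.42 ± 0.29 for Oas2 and -5.81 ± 0.29 for Rtp4, and Tlr7 had -8.30 ± 0.34. Fibroblast genes had 13 of 16 higher and 1 lower (adjusted p = 0.00120, adjusted p = 0.287 if estimated), with 3.28 ± 0.34 for Pdgfra. Erythroid and platelet genes had 6 of 6 higher (adjusted p = 1.4e-04, adjusted p = 0.168 if estimated). Of 16193 genes 3905 were higher and 1731 lower in cDC1, a share of 69.3% higher. Among calls with at least 10 CPM in the higher group it was 42.5% (965 and 1304).

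In cDC1 against pDC (n = 3 and 5) 27 of 27 were lower (adjusted p = 4.6e-52) of the pDC markers, with -10.72 ± 0.80 for Siglech and -5.50 ± 0.68 for Bst2, and 15 of 18 were higher (adjusted p = 9.8e-32, 15 higher and 1 lower within it) of the cDC1 markers. Factors had 4.75 ± 0.61 for Batf3, -7.67 ± 0.67 for Spib and -2.72 ± 0.30 for Ikzf2 and the conventional dendritic cell gene Zbtb46 5.22 ± 0.48. Costimulation genes had 12 of 16 higher and 1 lower (adjusted p = 7.2e-17, 13 higher and 1 lower within it). In all 1344 genes were higher and 1345 lower in cDC1 of 17066 (1181 and 1131 at 10 CPM or more). Without cDC1 replicates 1 to 3 in turn, 904, 943 and 910 were higher and 695, 741 and 713 lower. In cDC2 against pDC (n = 3 and 5) 26 of 27 were lower (adjusted p = 3.1e-34, adjusted p = 0.0822 if estimated) of the pDC markers and 12 of 20 were higher and 4 lower (adjusted p = 1.4e-06) of the cDC2 markers. Itgam had 5.25 ± 0.32, Spi1 3.39 ± 0.31 and Irf8 -4.03 ± 0.50. Proliferation genes were higher in cDC2: 19 of 20 were higher (adjusted p = 2.5e-19, adjusted p = 0.0882 if estimated, 20 higher and 0 lower within it) for G2 and M phase, with 5.21 ± 0.30 for Top2a. Fibroblast genes had 18 of 21 lower (adjusted p = 2.1e-05, adjusted p = 0.348 if estimated), with -7.19 ± 0.47 for Serpinh1. In all 2071 genes were higher and 4121 lower in cDC2 of 17752 (1851 and 1276 at 10 CPM or more). Without cDC2 replicates 1 to 3 in turn, 1536, 1523 and 1555 were higher and 1389, 1303 and 1361 lower. In pDC replicate 1, with 1838064 counts, Col1a1 stood at 1046 CPM, against 2.71 to 63.97 CPM in the others.

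Cocktail differences were set against splenic ones over genes tested in both, which share no library. The log2 fold changes of PIB against PIP and of cDC1 against cDC2 had r = -0.0467 and rho = -0.126 across 13664 genes, with 423 higher in both, 210 lower in both and 759 opposite, against 216, 132.7 and 365 genes if independent, or 415, 262 and 715 within genes called between the subsets. PIB against C9a.SII and cDC1 against pDC had r = 0.193 and rho = 0.0651 (r = 0.0567 without C9a.SII replicate 1 and rho = -0.00425 without pDC replicate 1). Of these genes 223 were higher in both, 0.802% lower in both and 264 opposite, against 82.8, 95.6 and 180.0 genes if independent, or 178, 123.5 and 298 within those called. PIP against C9a.SII and cDC2 against pDC had r = 0.161 and rho = 0.116 (r = 0.0839 and rho = 0.0554 without C9a.SII replicate 1), with 344 higher in both, 510 lower in both and 534 opposite, against 171, 246 and 412 genes if independent, or 269.5, 434 and 685 within those called. Genes are not independent replicates, so no p is given.

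Day 9 cells were compared with splenic counterparts next, cultured cells against spleen. In PIB against cDC1 (n = 5 and 3) Xcr1 stood at 141.7 ± 5.33 against 225 ± 23.9 CPM, not a called difference, while Clec9a stood at 0.0349 ± 0.0481 against 577 ± 25.5 CPM in a line whose Clec9a alleles carry Cre. Irf8 had -3.21 ± 0.23, Itgax -8.22 ± 0.16, H2-Aa -4.79 ± 0.18, Itgam 3.76 ± 0.14 and Bst2 4.29 ± 0.11. Of the cDC1 markers 15 of 19 were lower and 1 higher (adjusted p = 2.2e-25). Of the pan-dendritic genes 14 of 15 were lower (adjusted p = 1.2e-34). Of the class II genes 11 of 12 were lower (adjusted p = 6.8e-12, adjusted p = 0.0628 if estimated). Of the fibroblast genes 27 of 28 were higher (adjusted p = 6.0e-46). In all 4833 genes were higher and 6130 lower in PIB of 19061 (3735 and 1696 at 10 CPM or more). In PIP against cDC2 (n = 4 and 3) Itgam stood at 323 ± 51.6 against 237 ± 11.3 CPM and was not called. The others had -4.87 ± 0.17 for Ptprc, -3.43 ± 0.08 for Itgax, -7.83 ± 0.19 for H2-Aa, 2.22 ± 0.08 for Irf4 and 5.68 ± 0.16 for Prdm1. Of the cDC2 markers 13 of 20 were lower and 4 higher (adjusted p = 1.5e-05, adjusted p = 0.0622 if estimated). Of the pan-dendritic genes 13 of 15 were lower (adjusted p = 1.1e-23). Of the fibroblast genes 27 of 27 were higher (adjusted p = 1.0e-24). In all 4920 genes were higher and 4470 lower in PIP of 16771.

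In C9a.SII against pDC (n = 4 and 5) Siglech, which marks pDC, stood at 0.0478 ± 0.0955 against 2054 ± 652 CPM. Ptprc had -2.45 ± 0.29, Irf8 -3.67 ± 0.41, Bst2 -2.53 ± 0.45 and Ikzf2 4.32 ± 0.24. Of the pDC markers 26 of 27 were lower (adjusted p = 1.9e-28, adjusted p = 0.0843 if estimated). Of the class II genes 12 of 12 were lower (adjusted p = 6.3e-15, adjusted p = 0.0845 if estimated). Of the contractile genes 12 of 12 were higher (adjusted p = 4.2e-16, adjusted p = 0.0604 if estimated). In all 2862 genes were higher and 3062 lower in C9a.SII of 15518 (2610 and 1877 at 10 CPM or more). Without C9a.SII day 9 replicate 1, 3447 were higher and 4937 lower. In hCD2.SII against pDC (n = 3 and 5) Siglech stood at 0.0550 ± 0.0953 against 2107 ± 699.9 CPM. Ptprc had -2.15 ± 0.47, Irf8 -3.33 ± 0.57, Ikzf2 4.85 ± 0.37 and Clec9a -5.17 ± 0.62. Of the pDC markers 24 of 27 were lower (adjusted p = 5.4e-31, adjusted p = 0.0973 if estimated, 0 higher and 27 lower within it). Of the class II genes 12 of 12 were lower (adjusted p = 6.1e-17, adjusted p = 0.0973 if estimated). In all 2654 genes were higher and 3093 lower in hCD2.SII of 17439 (2444 and 1880 at 10 CPM or more). Without hCD2.SII day 9 replicates 1 to 3 in turn, 2096, 2120 and 2422 were higher and 1930, 1609 and 1989 lower.

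Days 9 and 3 were compared in double positive cells. In PIB (n = 5 and 4) the factors were not called, with 177 ± 39.1 against 156.6 ± 19.6 CPM for Spi1, 156.3 ± 50.1 against 126.3 ± 11.4 CPM for Irf8 and 20.8 ± 7.08 against 21.2 ± 0.620 CPM for Batf3, and neither was Xcr1, at 122.3 ± 4.58 against 113.6 ± 3.73 CPM. Class II genes rose: 6 of 9 were higher (adjusted p = 5.7e-09, adjusted p = 0.0617 if estimated). H2-Aa had 3.01 ± 0.19 and H2-Eb1 2.94 ± 0.30. Macrophage markers had 10 of 14 higher (adjusted p = 1.5e-09), with 4.03 ± 0.58 for Marco, and outside the lists the chemokine Cxcl13 had 5.44 ± 0.59. Proliferation genes fell: 19 of 20 were lower (adjusted p = 9.2e-24) for G2 and M phase and 9 of 20 were lower (adjusted p = 4.9e-08) for S phase. Cenpf had -2.69 ± 0.22 and Rrm2 -2.02 ± 0.18. Cholesterol genes had 5 of 18 lower (adjusted p = 3.3e-09). Fibroblast genes had 4 of 28 higher (adjusted p = 1.6e-07, adjusted p = 0.0895 if estimated). In all 577 genes were higher and 1330 lower on day 9 of 15702. The excess of lower genes shrank at 10 CPM or more and with a replicate block, and grew without a low-count filter. Without PIB day 3 replicate 4, 528 were higher and 875 lower. In PIP (n = 4 and 3) the factors were not called, with 319 ± 19.1 against 397 ± 73.2 CPM for Spi1, 377 ± 18.1 against 451 ± 49.02 CPM for Irf4 and 377 ± 38.8 against 499.6 ± 13.1 CPM for Prdm1. Class II genes had 4 of 9 higher (adjusted p = 8.0e-10, adjusted p = 0.0808 if estimated, 5 higher and 0 lower within it). H2-Aa had 4.58 ± 0.35 and H2-Eb1 4.48 ± 0.27. The cDC2 markers had 4 of 14 higher (adjusted p = 8.0e-05, adjusted p = 0.0734 if estimated), with 3.75 ± 0.30 for Cd209a. Fibroblast genes fell: 15 of 27 were lower (adjusted p = 1.4e-22, adjusted p = 0.148 if estimated, 0 higher and 16 lower within it). Col3a1 had -3.15 ± 0.32 and Fbln2 -3.01 ± 0.40. The splenic cDC1 set had 40 of 406 higher and 4 lower (adjusted p = 3.1e-04, adjusted p = 0.148 if estimated, 49 higher and 12 lower within it). In all 515 genes were higher and 467 lower on day 9 of 15823. Without PIP day 9 replicates 1, 2 and 4 in turn, 371, 368 and 393 were higher and 308, 243 and 279 lower.

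In C9a.SII (n = 4 and 4) the factors were not called, with 93.97 ± 35.8 against 139.1 ± 49.9 CPM for Spib, 200.3 ± 66.8 against 282 ± 97.6 CPM for Irf8 and 540.2 ± 146.4 against 876 ± 329.6 CPM for Ikzf2. The macrophage markers moved as a list: 1 of 11 was higher (adjusted p = 7.7e-16, adjusted p = 0.0521 if estimated, 6 higher and 0 lower within it), with Adgre1 at 19.4 ± 8.03 against 0.456 ± 0.310 CPM, a call lost without C9a.SII day 3 replicate 3 and without C9a.SII day 9 replicate 2 (5.05 to 5.31). In all 15 genes were higher and 1 lower on day 9 of 15541, and 1621 had an unadjusted p under 0.05. Leaving out day 3 replicates 1 to 4 in turn gave 1, 177, 0 and 3 higher and 0, 70, 0 and 0 lower. Leaving out day 9 replicates 1 to 4 in turn gave 94, 0, 1 and 1 higher and 21, 0, 0 and 0 lower. The counts were 344 and 185 without day 3 replicate 2, where Ptprc stood at 1.52 CPM, and day 9 replicate 1, when Spib and Ikzf2 were called lower, at -1.07 and -1.12. DESeq2 gave 1.02% higher and 57 lower. In hCD2.SII (n = 3 and 4) the factors were not called, with 124.7 ± 63.4 against 219.5 ± 46.4 CPM for Spib, 255 ± 110.5 against 478 ± 109.8 CPM for Irf8 and 788 ± 361 against 1273 ± 234 CPM for Ikzf2. Log2 fold changes were 2.19 ± 0.30 for Tlr2, -2.40 ± 0.27 for Cd24a and -2.49 ± 0.42 for Mcm5. S phase genes had 7 of 20 lower (adjusted p = 2.0e-08, adjusted p = 0.627 if estimated). The cDC2 markers had 4 of 13 higher (adjusted p = 0.00541, adjusted p = 0.627 if estimated). In all 719 genes were higher and 332 lower on day 9 of 16044. Fewer were higher at 10 CPM or more, both counts fell with a replicate block, and the fit of all groups gave more lower. Without day 3 replicates 3 and 4 in turn, 430 and 401 were higher and 181 and 169 lower. Without day 9 replicates 1 to 3 in turn, 1604, 376 and 384 were higher and 1066, 184 and 1.004% lower.

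Scores of double positive cells, day 9 minus day 3, were tested by exact two-sided permutation for 12 combinations of cocktail and set. None passed adjustment. The range in brackets is over leaving out each library. The fibroblast score changed by 0.64 (exact p = 0.00794, adjusted 0.0952, 0.53 to 0.76) in PIB, -1.30 (exact p = 0.0286, adjusted 0.114, -1.45 to -1.01) in PIP, -0.47 (exact p = 0.143, adjusted 0.238, -0.61 to -0.28) in C9a.SII and -1.05 (exact p = 0.314, adjusted 0.419, -2.16 to -0.42) in hCD2.SII. The pan-leukocyte score changed by 0.19 (exact p = 0.119, adjusted 0.238, 0.12 to 0.28) in PIB, 0.96 (exact p = 0.0286, adjusted 0.114, 0.49 to 1.19) in PIP, 0.80 (exact p = 0.0571, adjusted 0.137, 0.57 to 1.02) in C9a.SII and -0.42 (exact p = 0.0571, adjusted 0.137, -0.52 to -0.23) in hCD2.SII. Size factors of DESeq2 gave 0.04 in PIB. For the splenic set of the counterpart the changes were 0.09 (exact p = 0.159, adjusted 0.238, 0.05 to 0.13, -0.07 with DESeq2 size factors) for cDC1 in PIB, -0.0010 (exact p = 1.00, adjusted 1.00, -0.07 to 0.04, 0.01 with a prior count of 0.5) for cDC2 in PIP, 0.02 (exact p = 0.400, adjusted 0.480, 0.0039 to 0.04) for pDC in C9a.SII and 0.03 (exact p = 0.686, adjusted 0.748, -0.02 to 0.05) for pDC in hCD2.SII. On day 9 the cDC1 score was 3.02 ± 0.08 in PIB and 3.09 ± 0.08 in PIP, against 4.66 ± 0.01 in cDC1 and 2.45 ± 0.07 in C9a.MEF, cDC1 libraries having defined the set.

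**Figure D2:**
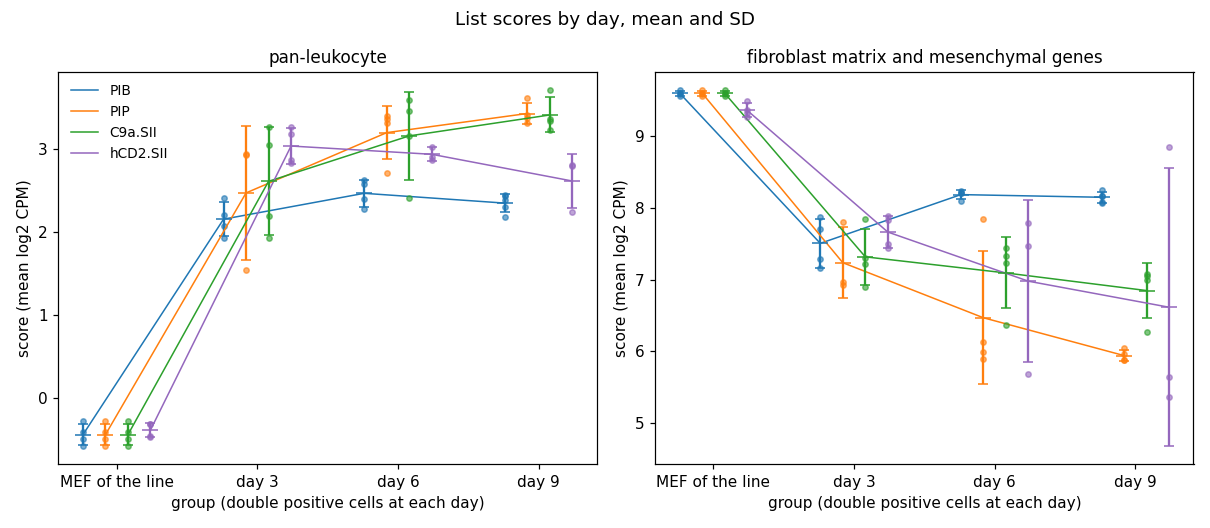
Scores of double positive cells by day (mean log2 CPM over a list, y axis; day or control group, x axis) for pan-leukocyte genes, left, and fibroblast matrix and mesenchymal genes, right. Points are libraries (n = 3 to 5 per group), lines join group means and bars are SD.

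Sort gates were compared at day 9, where Ptprc is the gate marker and no finding. Against cells sorted by the reporter alone, PIB double positive cells (n = 5 and 5) had Ptprc at 5.50 ± 0.38, Xcr1 at 1.53 ± 0.22 and Itgam at 2.26 ± 0.35. Class II genes had 7 of 9 higher (adjusted p = 2.4e-15, 8 higher and 0 lower within it). The cDC2 markers had 6 of 12 higher (adjusted p = 2.0e-14, 7 higher and 0 lower within it), with 2.47 ± 0.37 for Clec4a2. Pan-leukocyte genes had 5 of 17 higher (adjusted p = 3.5e-13, 7 higher and 0 lower within it). Macrophage markers had 6 of 14 higher (adjusted p = 1.5e-13, 8 higher and 0 lower within it), with the complement gene C1qb at 4.15 ± 0.67. The splenic cDC1 set had 17 of 397 higher and 2 lower (adjusted p = 3.4e-06, 19 higher and 3 lower within it). In all 0.940% of genes were higher and 0.762% lower of 15214. Without tdT+ replicate 1, 94 were higher and 94 lower. Without double positive replicates 1 and 4 in turn, 93 and 92 were higher and 80 and 75 lower. In PIP (n = 4 and 4) Ptprc had 5.12 ± 0.25, and only 2 genes were higher and 0 lower by edgeR of 16406, with 1839 at an unadjusted p under 0.05 and 38 higher and 30 lower by DESeq2. Without tdT+ replicates 1 to 4 in turn, 21, 1, 1 and 1 were higher and 16, 0, 0 and 0 lower. Without double positive replicates 1, 2 and 4 in turn, 1, 1 and 1 were higher and 0 lower each time. The second called gene, the gelatinase Mmp9, had 1.30 ± 0.17, a call lost without PIP day 9 tdT+ replicates 2, 3 or 4 and without PIP day 9 double positive replicates 1, 2, 3 or 4 (1.24 to 1.39).

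In C9a.SII (n = 4 and 4) Ptprc had 5.61 ± 0.27 against the reporter gate. Pan-leukocyte genes had 3 of 20 higher (adjusted p = 4.2e-21, 10 higher and 0 lower within it). Contractile genes had 4 of 12 higher (adjusted p = 1.9e-19). In all 18 genes were higher and 5 lower of 15586. Leaving out tdT+ replicates 1 to 4 in turn gave 21, 5, 7 and 7 higher and 8, 0, 0 and 1 lower. Leaving out double positive replicates 1 to 4 in turn gave 27, 10, 7 and 8 higher and 11, 3, 0 and 1 lower. In hCD2.SII (n = 3 and 4) Ptprc had 8.45 ± 0.59, and the transduced factors were higher too. Irf8 had 3.19 ± 0.31, Spib 3.39 ± 0.38 and Ikzf2 3.37 ± 0.33. Pan-leukocyte genes had 12 of 18 higher (adjusted p = 3.8e-15, adjusted p = 0.146 if estimated, 13 higher and 1 lower within it), with 5.81 ± 0.70 for Hcls1, and Cd74 had 4.38 ± 0.41. S phase genes had 14 of 20 lower (adjusted p = 9.6e-14, adjusted p = 0.146 if estimated, 0 higher and 15 lower within it), with -2.696 ± 0.36 for Mcm5. Cholesterol genes had 10 of 18 lower (adjusted p = 7.6e-11, adjusted p = 0.146 if estimated). In all 1306 genes were higher and 668 lower of 16173. Without YFP+ replicates 1 to 4 in turn, 989, 1004, 927 and 998 were higher and 395, 393, 359 and 370 lower. Without double positive replicates 1 to 3 in turn, 2571, 826 and 856 were higher and 2363, 316 and 346 lower.

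Against cells sorted by CD45 alone, PIB double positive cells (n = 5 and 4) had 2.09 ± 0.11 for Xcr1, 1.76 ± 0.17 for H2-Aa and 1.80 ± 0.25 for H2-Eb1. Class II genes had 5 of 10 higher (adjusted p = 5.3e-18, 6 higher and 0 lower within it). The cDC1 markers had 1 of 14 higher (adjusted p = 6.1e-06). Contractile genes had 3 of 12 lower (adjusted p = 1.3e-07, 0 higher and 5 lower within it). In all 66 genes were higher and 0.739% lower of 15839. Without CD45+ replicates 1 and 2 in turn, 60 and 75 were higher and 76 and 180 lower. Without double positive replicates 1 to 5 in turn, 50, 54, 49, 51 and 80 were higher and 48, 61, 44, 48 and 240 lower. In PIP (n = 4 and 4) H2-Eb1 had 2.36 ± 0.15 and the axon guidance receptor Robo2 -1.97 ± 0.17. Class II genes had 2 of 9 higher (adjusted p = 2.9e-10, adjusted p = 0.0887 if estimated, 3 higher and 0 lower within it). In all 76 genes were higher and 53 lower of 15732, but 24 and 1 in the fit of all groups and 32 and 22 at 10 CPM or more. In C9a.SII (n = 4 and 4) 5 genes were higher and 0 lower by edgeR of 15606, with 1223 at an unadjusted p under 0.05. DESeq2 gave 16 higher and 8 lower, and the fit of all groups far more of each. Without CD45+ replicates 1 to 4 in turn, 2, 0, 0 and 0 were higher. Without double positive replicates 1 to 4 in turn, 10, 0, 1 and 0 were higher. Each time 0 were lower. In hCD2.SII (n = 3 and 3) 0 genes were higher and 0 lower by edgeR of 15432, with 261 at an unadjusted p under 0.05 and 0 higher and 1 lower by DESeq2. With replicate number as a block the counts were 0 and 9. Without hCD2.SII day 9 double positive replicate 1, 0 were higher and 1 lower.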

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

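Tests of interferon-stimulated genes, the 3 libraries with another cocktail's factors and the fibroblast scores of PIB and PIP were chosen after the result was seen.

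PIB day 6 tdT+ replicate 4 held Irf4 at 539 CPM, PIP day 3 tdT+ replicate 5 Spib at 112.4 CPM and C9a.SII day 6 tdT+ replicate 5 Irf4 at 658 CPM. Each was a factor of another cocktail, in groups outside every comparison. Against a mixture with cells of another cocktail, the factor of the labelled cocktail stood at 9.76% at most of its mean in the other libraries (Batf3, at 1.45 CPM), a level that PIP libraries also reach, so a small admixture cannot be told apart. A wrong label stays open and is the better match: with the 7 factors left out, 3 of 3 correlated best across genes with a group of another cocktail, the first with PIP day 6 tdT+ (r = 0.989, against 0.955 for the best group of its own cocktail), the second with C9a.SII day 9 tdT+ (0.953 against 0.913) and the third with PIP day 3 double positive (0.983 against 0.960). No biological explanation was tested.

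Interferon-stimulated genes were lower in C9a.SII day 9 cells than in C9a.MEF, by 3.02 in mean log2 CPM (camera adjusted p = 2.0e-15, and 0.124 if estimated). In the hCD2 line the mean fall was 3.03, with 2 of 28 members called lower. The scores there were 5.65, 2.32 and 2.10 in replicates 1, 2 and 3 against 6.38 ± 0.09 in hCD2.MEF. A raised level in C9a.MEF alone is argued against by C9a.MEF minus hCD2.MEF, at -0.0688, and the shallow C9a.SII library by 24 members lower without it. An effect shared by all transduced, cultured and sorted cells is argued against as the whole cause, since on day 9 the score was below C9a.MEF (6.31 ± 0.03) by 0.91 in double positive PIB cells (5.40 ± 0.09) and was above it in PIP (6.57 ± 0.08). In SII cells it ran with the fibroblast score, at 8.84, 5.64 and 5.36 in these replicates, and stayed at 6.03 to 6.07 in hCD2.SII YFP+ cells (fibroblast score 9.11 to 9.24). An effect of SII may remain a hypothesis, found and tested on the same data. A level raised in both MEF lines, a differing share of cells that lost fibroblast genes or a smaller effect of transduction stays open and untested.

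More genes were higher in cDC1 than in cDC2 (3905 against 1731). Unequal depth is argued against, since 67.8% of calls were higher after every library was thinned to 4549864 counts, and so is RNA of fibroblasts, since the difference in CPM over 16 fibroblast genes (13 higher, adjusted p = 0.287 if estimated) ran against their level in MEFs (Spearman's rho = -0.579), with Col1a1 at 6.00 against 10.3 and Fn1 at 9.02 against 38.3 CPM. At 10 CPM or more 42.5% of calls were higher, so the excess lay below. Genes detected were 35454 to 37010 in cDC1 and 27557 to 29179 in cDC2. A broad low-level signal over genes silent in these cells goes with both. Because 42.5% lay outside both ranges set beforehand, it cannot be told from a difference between the subsets, which stays open and untested.

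C9a.MEF replicate 4 had 12968294 counts, far above the other 3 libraries (10878799 to 11201692), as did PIB day 9 CD45+ replicate 2, at 14012646 against 6912082 to 7811553, while C9a.SII day 9 double positive replicate 1 had a fibroblast score of 6.27, far below the others (6.995 to 7.07). These were 3 of 64 groups and measures examined, and chance alone singles out about 1 in 20. The change by SII differed between the lines for 32 genes higher and 69 lower in the C9a line, but 78 and 29 in a fit of all groups and 607 and 204 without hCD2.SII day 9 replicate 1. The fibroblast score changed, day 9 minus day 3, by 0.64 in PIB, with 5 of 5 day 9 libraries above every day 3 library. In PIP it changed by -1.30, with 4 of 4 below, a difference of 1.94. Neither change passed adjustment, which no single test with this many libraries could. The exact permutation p (0.0188 over 4410 permutations) did not test equal change in both, so it cannot decide the difference.

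In 23 of 27 comparisons under 5% of splits of the libraries into same-sized groups called as many genes, unadjusted. The splits with as many calls as the real one, itself included, follow with its count (to 2 digits if written as 1.3e+02) and, in brackets, the highest other: 1 of 35 for PIP v MEF 4650 (0), C9a.SII v MEF 3346 (0), hCD2.SII v MEF 3164 (0), PIP v C9a.SII 3524 (0), PIP day 9 v day 3 982 (0), hCD2.SII day 9 v day 3 1051 (9), C9a.SII v reporter gate 23 (0), hCD2.SII v reporter gate 1974 (0), PIP v CD45 gate 1.3e+02 (5), C9a.SII v CD45 gate 5 (0), PIP v cDC2 9390 (0). 1 of 56 for cDC1 v pDC 2689 (0), cDC2 v pDC 6192 (796), PIB v cDC1 10963 (0), hCD2.SII v pDC 5747 (0). 1 of 100 for PIB v MEF 3438 (2092), PIB v PIP 3397 (1860), PIB v C9a.SII 2968 (1226), PIB day 9 v day 3 1907 (805), PIB v reporter gate 259 (8), C9a.SII v pDC 5924 (3890). 2 of 100 for PIB v CD45 gate 183 (264), the line difference 1.0e+02 (318). Chance is not argued against for C9a.SII day 9 v day 3 (2 of 35, 16 against 1.2e+02) and PIP v reporter gate (2 of 35, 2 against 11). There and in the line difference, whose splits do not test equal change, a split called several times the real count. What libraries grouped by that split share was not tested. The 10 splits of 3 against 3 are too few for cDC1 v cDC2 (1 of 10, 5636 against 0) and hCD2.SII v CD45 gate (10 of 10, 0 against 0).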

How the results depend on the processing

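Calls of at least 10 CPM in the higher group, comparisons without 3 libraries of low total or low Ptprc, splenic sets of genes at 10 CPM or more, and correlations that left out 1 library were chosen after the data were seen. Every alternative planned in advance was run. A count moved where it differed by over 1.5 times from the main count, which stands in brackets. Counts written as 1.2e+02 are rounded to 2 digits. Cells are day 9 double positive cells unless a gate or day is given, and the line difference is the SII change in the C9a line minus that in the hCD2 line.

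With DESeq2 size factors, 0 of 54 counts moved, and all 285 named gene values and every list test kept their side of the threshold. These factors shifted the median log2 fold change by over 0.1 only in hCD2.SII v pDC (0.13), and the line difference became 46 higher and 63 lower. The splenic cDC1-specific score difference of PIB cells, day 9 minus day 3, turned from 0.09 to -0.070 under these factors, and the cause was not tested. With a prior count of 0.5 that of PIP cells for cDC2 turned from -0.0010 to 0.0064.

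Calls of at least 10 CPM are by construction part of the main calls, and 36 of 54 counts moved. cDC1 v cDC2 965 higher (3905), cDC2 v pDC 1276 lower (4121), PIB v MEF 974 higher (1644) and 886 lower (1794), PIP v MEF 1399 higher (2379) and 1307 lower (2271), C9a.SII v MEF 898 higher (1638) and 1077 lower (1708), hCD2.SII v MEF 973 higher (1780) and 839 lower (1384). PIB v PIP 917 higher (1665) and 815 lower (1732), PIB v C9a.SII 885 higher (1375) and 674 lower (1593), PIP v C9a.SII 1134 higher (1715) and 978 lower (1809), PIB day 9 v day 3 316 higher (577) and 370 lower (1330), PIP day 9 v day 3 271 higher (515) and 221 lower (467), C9a.SII day 9 v day 3 0 lower (1). hCD2.SII day 9 v day 3 285 higher (719), PIB v reporter gate 66 higher (1.4e+02) and 66 lower (1.2e+02), hCD2.SII v reporter gate 709 higher (1306) and 367 lower (668), PIB v CD45 gate 39 higher (66) and 38 lower (1.2e+02), PIP v CD45 gate 32 higher (76) and 22 lower (53), PIB v cDC1 1696 lower (6130). PIP v cDC2 2739 higher (4920) and 2720 lower (4470), C9a.SII v pDC 1877 lower (3062), hCD2.SII v pDC 1880 lower (3093), the line difference 45 lower (69).

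Without a low-count filter more genes were tested, 24 of 54 counts moved and the median log2 fold change shifted by up to -1.32, in C9a.SII v pDC. cDC1 v cDC2 8069 higher (3905) and 2714 lower (1731), cDC2 v pDC 3186 higher (2071), PIB day 9 v day 3 2273 lower (1330), PIP day 9 v day 3 783 lower (467), C9a.SII day 9 v day 3 98 higher (15) and 29 lower (1), hCD2.SII day 9 v day 3 1462 higher (719) and 541 lower (332). PIP v reporter gate 57 higher (2) and 97 lower (0), C9a.SII v reporter gate 1.3e+02 higher (18) and 75 lower (5), hCD2.SII v reporter gate 1036 lower (668), PIB v CD45 gate 120 higher (66) and 505 lower (1.2e+02), PIP v CD45 gate 1.2e+02 higher (76), C9a.SII v CD45 gate 14 higher (5) and 3 lower (0). hCD2.SII v CD45 gate 2 higher (0) and 48 lower (0), PIB v cDC1 12656 lower (6130), C9a.SII v pDC 8942 lower (3062), the line difference 55 higher (32). No named gene changed its call and 4 list tests gained one. Correlations across genes, which are not independent, became r = -0.125 and rho = -0.178 for PIB minus PIP with cDC1 minus cDC2, r = 0.122 for PIB minus C9a.SII with cDC1 minus pDC, and r = 0.0381 and rho = 0.0223 for PIP minus C9a.SII with cDC2 minus pDC. Over genes called in the splenic comparison the first pair had r = -0.0124 and rho = -0.0487 and the second rho = 0.131. Leaving out the 7 transduced factors moved none of the 6 values by more than its spread.

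The DESeq2 test moved 14 of 54 counts and no call of a named gene, and the cause was not tested. C9a.SII day 9 v day 3 1.6e+02 higher (15) and 57 lower (1), PIB v reporter gate 188 lower (1.2e+02), PIP v reporter gate 38 higher (2) and 30 lower (0), C9a.SII v reporter gate 68 higher (18) and 52 lower (5), hCD2.SII v reporter gate 1042 lower (668), PIB v CD45 gate 261 lower (1.2e+02). C9a.SII v CD45 gate 16 higher (5) and 8 lower (0), hCD2.SII v CD45 gate 1 lower (0), the line difference 1.2e+02 higher (32) and 1.4e+02 lower (69).

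Replicate number as a block moved 18 of 54 counts, ended the call of Mmp9 (PIP v reporter gate) and gave 2 list tests a call, and it changed no other call of a named gene or list. In 24 of 26 comparisons the libraries share only a number, and only in PIP day 9 v day 3 and PIB v cDC1 did each pair of them correlate best with each other. Why counts moved was not tested. cDC2 v pDC 3212 higher (2071), PIB day 9 v day 3 770 lower (1330), PIP day 9 v day 3 341 higher (515) and 190 lower (467), C9a.SII day 9 v day 3 2 higher (15) and 0 lower (1), hCD2.SII day 9 v day 3 321 higher (719) and 1.4e+02 lower (332), PIP v reporter gate 1 higher (2). C9a.SII v reporter gate 4 higher (18) and 2 lower (5), hCD2.SII v reporter gate 540 higher (1306) and 1.2e+02 lower (668), PIB v CD45 gate 198 lower (1.2e+02), C9a.SII v CD45 gate 0 higher (5), hCD2.SII v CD45 gate 9 lower (0), the line difference 6 higher (32) and 11 lower (69).

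Fitting all 41 groups together, with a spread shared by every library (the 3 with factors of another cocktail and all day 6 groups included), moved 26 of 54 counts and ended the call of Mmp9, and the cause was not tested. cDC1 v cDC2 3583 lower (1731), cDC1 v pDC 2516 lower (1345), cDC2 v pDC 4015 higher (2071) and 7877 lower (4121), PIP day 9 v day 3 271 higher (515) and 244 lower (467), C9a.SII day 9 v day 3 384 higher (15) and 49 lower (1), hCD2.SII day 9 v day 3 612 lower (332). PIB v reporter gate 71 higher (1.4e+02) and 50 lower (1.2e+02), PIP v reporter gate 1 higher (2) and 1 lower (0), C9a.SII v reporter gate 241 higher (18), hCD2.SII v reporter gate 1142 lower (668), PIP v CD45 gate 24 higher (76) and 1 lower (53), C9a.SII v CD45 gate 354 higher (5) and 58 lower (0). hCD2.SII v CD45 gate 1 lower (0), C9a.SII v pDC 5282 higher (2862) and 7167 lower (3062), hCD2.SII v pDC 4930 higher (2654) and 5766 lower (3093), the line difference 78 higher (32) and 29 lower (69).

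Leaving out 1 library at a time moved 25.9% of 444 counts. Ranges where any moved follow. cDC1 v pDC 695 to 1791 lower, cDC2 v pDC 1303 to 4181 lower, hCD2.SII v MEF 1320 to 3071 higher and 939 to 2762 lower, PIB day 9 v day 3 875 to 1664 lower, PIP day 9 v day 3 243 to 503 lower. C9a.SII day 9 v day 3 0 to 177 higher and 0 to 70 lower, hCD2.SII day 9 v day 3 376 to 1604 higher and 1.6e+02 to 1066 lower, PIB v reporter gate 92 to 209 higher and 75 to 1.5e+02 lower, PIP v reporter gate 1 to 21 higher and 0 to 16 lower, C9a.SII v reporter gate 5 to 27 higher and 0 to 11 lower. hCD2.SII v reporter gate 826 to 2571 higher and 316 to 2363 lower, PIB v CD45 gate 44 to 240 lower, C9a.SII v CD45 gate 0 to 10 higher, hCD2.SII v CD45 gate 0 to 1 lower, C9a.SII v pDC 2549 to 4937 lower. hCD2.SII v pDC 1609 to 3539 lower, the line difference 15 to 607 higher and 31 to 204 lower. Of 2357 named gene values 9 lost and 1 gained a call, and 7 of 1332 list tests gained one. Interferon-stimulated genes in the line difference turned direction without hCD2.SII day 9 replicate 1 (camera adjusted p = 2.0e-14, and 0.367 at most over the libraries). The PIP cDC2-specific score difference ranged from -0.0716 to 0.0385 and the hCD2.SII pDC-specific one from -0.0173 to 0.0512. Correlations across genes ranged over r = -0.0767 to -0.0159 and rho = -0.149 to -0.0962 for the first pair, r = 0.0567 to 0.221 and rho = -0.0043 (without pDC replicate 1) to 0.107 for the second, and r = 0.0839 to 0.183 and rho = 0.0554 to 0.147 for the third.

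Without the libraries of low total or low Ptprc, 7 of 22 counts moved, and 2 named gene values and 2 of 39 list tests gained a call. C9a.SII day 9 v day 3 344 higher (15) and 185 lower (1), C9a.SII v reporter gate 11 lower (5), C9a.SII v CD45 gate 10 higher (5), C9a.SII v pDC 4715 lower (3062), the line difference 74 higher (32) and 1.2e+02 lower (69). At 4-fold the splenic sets held 232 cDC1-specific, 285 cDC2-specific and 409 pDC-specific genes, and without 1 splenic library the pDC-specific set held 509 to 958. No list test of these sets changed its call at 4-fold or 10 CPM. With a correlation between genes estimated per list, 64 list tests lost their call, 54 kept it and 26 had none.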

Other observations

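Day 6 entered no comparison, so levels are given. Xcr1 stood at 138.6 ± 16.04 CPM in PIB double positive cells on day 6 (n = 4), 66.97 ± 14.5 CPM in the CD45 gate (n = 3) and 30.5 ± 20.6 CPM in the tdT+ gate (n = 4, with 0 in replicate 4, the library labelled PIB that held Irf4), and at under 1 CPM on average in every PIP and SII group of that day. The class II chain H2-Aa followed the same order in PIB, at 53.5 ± 3.65, 20.1 ± 4.77 and 7.34 ± 1.45 CPM, the last again with that library, at 5.20 CPM. Siglech averaged under 1 CPM in all 12 groups of day 6. In hCD2.SII Clec9a reached 5.10 ± 3.54 CPM in double positive (n = 3) and 4.27 ± 1.28 CPM in CD45+ cells (n = 4), but 0.192 ± 0.270 CPM in YFP+ cells (n = 4). In the C9a line, whose Clec9a alleles carry Cre, it averaged under 0.2 CPM in every day 6 group and is not comparable.

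Ptprc was nearly absent from 2 libraries of a CD45 gate, PIP day 3 CD45+ replicate 5 (1.71 CPM) and C9a.SII day 3 double positive replicate 2 (1.52 CPM). Olfactory and vomeronasal receptor genes took 2.57% of the counts in pDC replicate 1. Ikzf2 stood at 70.5 CPM in PIP day 6 CD45+ replicate 4.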
